A study of Homo sapiens with 15 samples.

How the data were processed

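The deposited signal table gave, per the file headers, a signal intensity and a detection p-value for each of 48107 probes on 15 arrays. According to the labels, RNA was isolated with a Qiagen kit, turned into biotinylated cRNA with the Ambion MessageAmp kit and hybridized to Illumina HumanHT-12 arrays. The intensity values deposited by the authors already matched between arrays, with medians of 114 to 115, 75th percentiles of 194 to 195 and lowest values of 70.7 to 77.8, so they had been normalized between arrays before they were deposited, and they still held background. Array 1 of 100 nM AG014699 was deposited as whole numbers only, unlike the other 14, and was used like them. The detection p-value of each probe was used as deposited by the authors; the headers name it and do not give its formula. The second table deposited by the authors held log2 values, which equalled the log2 of the intensity minus the mean log2 of the probe to within 1e-07 for all 13867 complete probes of 24245, with blanks where the detection p-value was at least 0.01. All columns of both tables were used. 2 probes with 8 missing signals were left out, which left 48105.

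Samples were grouped by the treatment and dose in the labels into DMSO, 10 nM AG014699, 100 nM AG014699, LY294002, and 100 nM AG014699 with LY294002, with 3 arrays each. Replicate numbers came from the titles, because the replicate entry of the characteristics was constant within a group and served as a code of the group. The gene lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined.

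R 4.3.3 with limma 3.58.1 and statmod 1.5.0 was used. The intensities were background corrected, quantile normalized and turned to log2 with neqc (offset 16, background inferred from the detection p-values). Probes detected at p under 0.05 on at least 3 of the 15 arrays were kept, 23680 in all. Gene symbols came from the annotation table of the array, dated 2016, with 17507 probes matched to current gene entries and 0 symbols changed by the match. Of the kept probes 16577 carried 1 symbol, 7103 had no single gene name and were tested apart, and 5 annotated probes with several symbols were not given a gene. For each of 3365 genes with several probes the one with the highest mean log2 signal was used, which left 12302 genes.

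A limma model with 1 mean per group was fitted to all 15 arrays (lmFit and eBayes, 10 residual and 4.8 prior degrees of freedom), with 8 comparisons: 7 between pairs of groups and the interaction, that is, the change by LY294002 at 100 nM AG014699 minus that without AG014699. P-values were adjusted by Benjamini-Hochberg over genes within a comparison, and an adjusted p under 0.05 was called. The words rose and fell are used for genes that passed. Genes undetected on all 3 arrays of a group are given as at least so many fold, from the detection floor.

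The 28 gene lists held 761 distinct members, of which 599 were measured and 32 were in more than 1 list; they were written from general knowledge, and they are not a database release. Lists with at least 5 measured members, 27 in all, were tested with camera (preset correlation 0.01), with p-values adjusted over lists within each of 6 comparisons, and again with the correlation estimated from the data. The adjusted p of each called list was larger with the estimated correlation, often by orders of magnitude. Beside the number of members that passed over all genes, the number that passed when p-values were adjusted over the list alone is given. A list of 24 RNAs without a poly(A) tail, a list of acute phase genes and a list of immediate early genes were added after the values were seen. Where the median, the mean and the test of a list differed in sign, the list had not passed.

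The similarity of responses was given by the correlation and covariance of log2 changes over genes and by shared calls, beside 100 simulations in which groups did not differ from the shared DMSO arrays. Splits of the arrays were counted for each comparison, and for the interaction also after the additive effect of each drug was taken out of the values. Alternatives changed the background correction, the normalization, the source of the values, the filter, the choice of probe, the arrays, the groups in the fit, the weights of arrays, the variance model and the list test. The procedure was tested on simulated data: of genes set to change by 0.5, 1 and 2 log2 units, 4 of 67, 49 of 67 and 66 of 66 were recovered, with 7 false calls among 126, 0 calls in a comparison without change, and the 1 shifted list called with 0 others. The simulated genes were drawn independently, without correlation between genes or structure between arrays. False calls of lists or genes that stem from such correlation were therefore not tested.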

Results

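Gene expression was measured in MDA-MB-436, a human breast cancer cell line that lacks functional BRCA1, on 15 Illumina HumanHT-12 bead arrays. The cells had been treated for 7 days with the solvent DMSO, with AG014699 at 10 or 100 nM, with LY294002, or with 100 nM AG014699 and LY294002 together, which is called the combination here. AG014699, also named rucaparib, inhibits the DNA repair enzyme PARP1, and LY294002 inhibits the growth factor signalling kinase PI3K. Each of the 5 groups held 3 arrays, and the concentration of LY294002 was not given in the sources used here. Between 18971 and 20808 of 48105 probes were detected per array. After the filter on dim probes, 12302 genes were tested. Log2 signals of arrays of the same group correlated at 0.979 to 0.992 across these genes, and those of different groups at 0.959 to 0.988. Genes are not independent replicates. All changes below are differences of group means of normalized log2 signals, 3 arrays against 3, with the standard error (SE) of the fit to all 15 arrays, so that a gene has the same SE in every comparison of a pair of groups. The labels call the arrays triplicates and do not say whether these were separate cultures, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

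AG014699 at 10 nM, compared with DMSO, raised genes of secreted inflammatory proteins most. CSF3, which encodes granulocyte colony-stimulating factor, rose from a mean log2 signal of 6.65 ± 0.13 to 10.23 ± 0.12 (SD, n = 3 each), a log2 change of 3.59 (SE 0.16, adjusted p = 4.23e-09). IL24, a cytokine gene that no DMSO array detected, was at least 7.52-fold higher (adjusted p = 1.02e-07). PTGS2, the gene of the prostaglandin-forming enzyme cyclooxygenase 2, rose by 2.88 (SE 0.32), the chemokine genes CCL20 and CXCL2 by 2.73 (SE 0.12) and 2.53 (SE 0.19), and the interleukin 1 beta gene IL1B by 2.66 (SE 0.12). The hyaluronan-binding protein gene TNFAIP6 rose by 2.70 (SE 0.17) and the interleukin 13 decoy receptor gene IL13RA2 by 2.56 (SE 0.20). Among the genes that fell were S100A4, a calcium-binding protein gene, at -1.93 (SE 0.17), and GFRA1, a receptor for the neurotrophic factor GDNF, at -1.44 (SE 0.18). TMEFF2 fell at -1.50 (SE 0.18), the coagulation inhibitor gene TFPI at -1.28 (SE 0.14) and the procollagen processing gene PCOLCE at -1.26 (SE 0.19). In all, 292 genes changed, 214 higher and 78 lower, at an adjusted p under 0.05 in limma, and 1555 had an unadjusted p under 0.05. The count was 160, 152 and 174 without DMSO array 1, 2 or 3, and 173, 140 and 162 without array 1, 2 or 3 of the 10 nM group. It was 508 with array weights and 98 with the 5 arrays numbered 1 dropped.

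Among the gene lists fixed in advance, the inflammatory and secretory list moved most at 10 nM. Of its 30 measured members 16 rose (17 adjusted over the list alone) and the other 14 did not pass the test over all genes. The median log2 change was 0.85 (camera adjusted p = 1.26e-30, and 2.06e-05 with an estimated correlation). Beyond the genes above, the members that rose included IL6 at 2.38 (SE 0.14), the neutrophil chemoattractant genes CXCL8 at 1.94 (SE 0.13) and CXCL1 at 2.30 (SE 0.15), and TNFAIP3, a feedback inhibitor of NF-kB signalling, at 1.14 (SE 0.16). Of 22 genes of MAPK feedback 6 rose (9 adjusted over the list alone; adjusted p = 3.01e-06), among them the transcription factor gene EGR1 at 1.53 (SE 0.14) and PHLDA1 at 0.85 (SE 0.14). Of 19 histone genes 5 rose (6 adjusted over the list alone; median 0.28, adjusted p = 1.05e-05), with H2BC21 at 1.00 (SE 0.15) and H2AC18 at 0.73 (SE 0.11), calls that ended when the 5 arrays numbered 1 were dropped together (adjusted p = 0.0687 and 0.0628). Beside them, 24 RNAs that carry no poly(A) tail, a list chosen after the values were seen, had a median change of 0.37, and 6 of them rose. Of 27 FOXO target genes 4 rose (7 adjusted over the list alone, and 1 fell; adjusted p = 0.000361), among them FBXO32, a ubiquitin ligase gene of muscle wasting, at 0.86 (SE 0.12).

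Further lists shifted at 10 nM with few or no members past the test. The hypoxia-responsive genes ADM and NDRG1 rose by 1.07 (SE 0.11) and 1.10 (SE 0.14), the 2 called members of 29 in the glycolysis and hypoxia list (2 adjusted over the list alone; adjusted p = 0.00172). In the amino acid stress list of ATF4 targets, 2 of 31 genes rose (7 adjusted over the list alone; adjusted p = 0.00172), with the secreted glycoprotein gene STC2 at 0.82 (SE 0.11). The fatty acid synthesis list lay lower at a median of -0.25 (adjusted p = 0.00015) and the cholesterol synthesis list at -0.21 (adjusted p = 0.00108). With limma 0 of the 13 and 0 of the 20 genes passed, 6 and 5 were lower at an unadjusted p under 0.05, and 0 and 1 fell when adjusted over the list alone. The FASN change was -0.49 (SE 0.20, adjusted p = 0.297). The lists of mitosis (44 genes, median -0.18, adjusted p = 0.000361), lysosome and autophagy (33 genes, median 0.13, adjusted p = 0.000864) and luminal breast markers (7 genes, median 0.32, adjusted p = 0.0169) also passed camera with its preset correlation. With an estimated correlation the adjusted p was 0.0501 for mitosis, 0.0501 for lysosome and autophagy and 0.148 for luminal markers, while the other 8 of the 11 called lists held. Luminal markers had an adjusted p of 0.0534 without DMSO array 2 and of 0.0564 without array 1 of the 10 nM group.

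**Figure D1:**
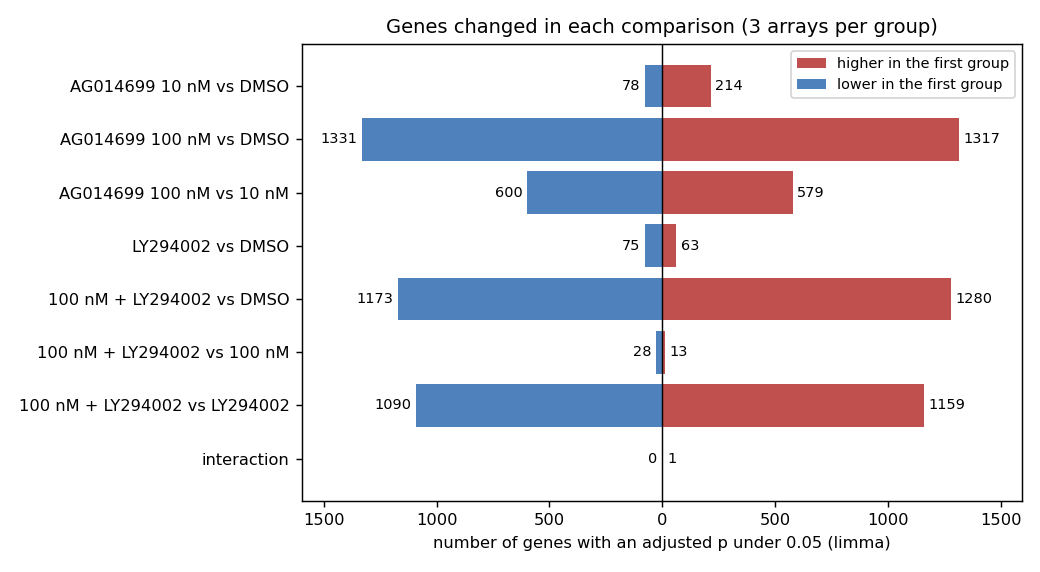
Bars show the number of genes higher (right of 0) and lower (left of 0) at an adjusted p under 0.05 in each of the 8 comparisons, out of 12302 genes tested on 15 arrays. The counts run from 1 gene in the interaction of AG014699 and LY294002 to 1317 higher and 1331 lower at 100 nM AG014699 against DMSO.

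AG014699 at 100 nM changed many more genes against DMSO. MMP1, the gene of interstitial collagenase, rose from a mean log2 signal of 5.90 ± 0.29 to 10.21 ± 0.33 (SD, n = 3 each), a change of 4.32 (SE 0.29) or 19.9-fold (adjusted p = 8.78e-08). IL24 was at least 14.0-fold higher (adjusted p = 2.91e-09). ESM1, the gene of the secreted proteoglycan endocan, rose by 3.41 (SE 0.20), IL13RA2 by 3.65 (SE 0.20), the lipase inhibitor gene G0S2 by 3.16 (SE 0.18) and the trypsin inhibitor gene SPINK1 by 2.88 (SE 0.15). The chemokine genes CCL3 and CCL3L3 rose by 3.49 (SE 0.22) and 3.70 (SE 0.13) and the defensin gene DEFB103A by 3.17 (SE 0.14); each has a near-identical copy, so their probes may not tell the copies apart. The largest falls were in CFI, the gene of complement factor I, at -3.42 (SE 0.20) and S100A4 at -3.09 (SE 0.17). S100A8 and S100A9, which encode the subunits of calprotectin, fell at -2.62 (SE 0.20) and -2.60 (SE 0.16), and CCL2, a chemoattractant of monocytes, at -2.59 (SE 0.19). TFPI, the keratin gene KRT80 and the matrix protein gene TGFBI fell at -2.35 (SE 0.14), -2.23 (SE 0.18) and -2.09 (SE 0.15). In all, 2648 genes changed, 1317 higher and 1331 lower, and 550 changed at least 2-fold. The size of the changes depended on the background correction: the 2-fold count was 193 with quantile normalization only, 251 with normexp background, 188 in the authors' value table and 191 with the signals as deposited. Of 809 called genes with several probes, 10 had a probe called in the other direction.

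Of the 30 inflammatory and secretory genes 20 rose and 2 fell at 100 nM (21 and 3 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 2.42e-10). Besides MMP1, CSF3 rose by 2.86 (SE 0.16), IL1B by 2.66 (SE 0.12), CXCL8 by 2.05 (SE 0.13), the stromelysin gene MMP3 by 2.02 (SE 0.25) and IL6 by 1.20 (SE 0.14), while CCL2 fell. Of 19 histone genes 12 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.92, adjusted p = 1.75e-09). H2BC8, H2AC18, H2BC21 and H4C8 rose by 2.23 (SE 0.15), 2.17 (SE 0.11), 2.15 (SE 0.15) and 1.99 (SE 0.18), and H2BC9 fell at -0.85 (SE 0.17); these copies resemble each other closely. Beside them, 19 of the 24 RNAs without a poly(A) tail rose, with a median of 1.25, among them RN7SK at 2.21 (SE 0.18), whereas RN7SL1 was at 0.10 (SE 0.13, adjusted p = 0.624); that list and both RNAs were chosen after the values were seen. MAPK feedback genes rose in 10 of 22 cases and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.000332), with FOS at 2.39 (SE 0.24), EGR1 at 2.02 (SE 0.14) and the MAPK phosphatase gene DUSP6 at 1.51 (SE 0.21).

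FOXO targets rose in 9 of 27 cases and fell in 1 at 100 nM (10 and 1 adjusted over the list alone; adjusted p = 0.00143), with FBXO32 at 1.28 (SE 0.12) and the insulin receptor substrate gene IRS2 at 1.11 (SE 0.17). Of 25 p53 target genes 9 rose and 2 fell (10 and 4 adjusted over the list alone; adjusted p = 0.00332). ATF3 rose by 1.72 (SE 0.13), CDKN1A, which encodes the cell cycle inhibitor p21, by 1.41 (SE 0.18) and GADD45A by 0.91 (SE 0.13). In the lysosome and autophagy list 10 of 33 genes rose (12 adjusted over the list alone; adjusted p = 0.00296, and 0.067 with an estimated correlation), among them the lysosomal channel gene MCOLN1 at 1.71 (SE 0.20) and the cholesterol transporter gene NPC1 at 1.20 (SE 0.15). The ribosome biogenesis and MYC list, with 2 of 26 genes higher (2 adjusted over the list alone), among them RRP12 at 1.11 (SE 0.14), had an adjusted p of 0.0338, of 0.0751 with an estimated correlation and of 0.1 without array 1 of the 100 nM group. It was 0.0536 with the authors' value table, 0.0612 with a strict filter and 0.0917 with the 5 arrays numbered 1 dropped.

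The fatty acid synthesis genes fell together at 100 nM: 12 of 13 were lower (13 adjusted over the list alone), with a median of -0.92 (camera adjusted p = 4.13e-10). SREBF1, the gene of a transcription factor that activates this pathway, fell at -1.80 (SE 0.22), the stearoyl-CoA desaturase gene SCD at -1.56 (SE 0.13), the desaturase gene FADS1 at -1.29 (SE 0.12) and the synthase gene FASN at -1.25 (SE 0.20). Of 20 cholesterol synthesis genes 8 fell (9 adjusted over the list alone; median -0.35, adjusted p = 0.00332), among them INSIG1, whose product retains the activators of this pathway in the endoplasmic reticulum, at -1.19 (SE 0.12) and the sterol reductase gene DHCR7 at -0.95 (SE 0.14). Of 37 interferon response genes 13 fell and 2 rose (15 and 4 adjusted over the list alone; adjusted p = 0.00303), with IFI44L at -1.85 (SE 0.26). The tetherin gene BST2 was at -1.03 (SE 0.15) and, the other way, IRF7 at 0.62 (SE 0.14). Of 12 epithelial markers 6 fell and 1 rose (6 and 2 adjusted over the list alone; adjusted p = 0.00238). The tight junction gene CLDN1 was at -1.64 (SE 0.18), ELF3 at -1.43 (SE 0.13), LCN2 at -1.47 (SE 0.23) and EPCAM at 0.76 (SE 0.17). Extracellular matrix and mesenchymal genes fell in 9 of 25 cases and rose in 4 (9 and 5 adjusted over the list alone; adjusted p = 0.0201). The collagen gene COL5A1 fell at -1.77 (SE 0.17), and SNAI2, which encodes the transcription factor Slug and was undetected on DMSO arrays, was at least 2.91-fold higher (adjusted p = 5.69e-05). In the mitosis list 6 of 44 genes fell and 1 rose (6 and 0 adjusted over the list alone), with KIF20A at -0.64 (SE 0.15). The adjusted p of this list was 0.0454, 0.251 with an estimated correlation, and 0.108, 0.0518, 0.104 and 0.0641 without DMSO array 2, DMSO array 3, and array 2 or 3 of the 100 nM group, and it was 0.0714 with the strict filter. For the matrix list it was 0.0659 with every probe tested on its own, and the IRF7 call ended with the arrays numbered 1 dropped (adjusted p = 0.0694).

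The lists of DNA repair and of both drug targets did not pass camera at 100 nM. PARP1, the target of AG014699, lay at -0.53 (SE 0.15, adjusted p = 0.0212). The adjusted p was 0.0676, 0.0764 and 0.0745 without DMSO array 2, DMSO array 3 or array 1 of the 100 nM group, and 0.00238 to 0.101 under the other settings. The PARP1 change itself was -0.329 without array 1 of the 100 nM group, and -0.633 and -0.641 without its array 2 or 3. BRCA1 was at 0.46 (SE 0.21, adjusted p = 0.133). The PARP family had 3 lower genes of 16 (3 adjusted over the list alone; adjusted p = 0.408), among them PARP9 at -1.05 (SE 0.14). Homologous recombination and Fanconi genes had 2 higher and 3 lower of 31 (2 and 1 adjusted over the list alone; adjusted p = 0.596), base excision and single-strand break repair 3 higher and 1 lower of 19 (3 and 1; adjusted p = 0.786). Non-homologous end joining had 2 lower genes of 11 (2 adjusted over the list alone; adjusted p = 0.786). DNA replication genes were higher in 6 and lower in 2 of 42 (6 and 2; adjusted p = 0.177), with the helicase gene MCM2 at 1.09 (SE 0.26). PI3K pathway components had 1 higher gene of 22 (0 adjusted over the list alone; adjusted p = 0.616).

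Most other lists that did not pass camera at 100 nM held members that moved both ways. Glycolysis and hypoxia genes were higher in 3 and lower in 5 of 29 cases (3 and 5 adjusted over the list alone; adjusted p = 0.517). ATF4 targets were higher in 7 and lower in 4 of 31 (8 and 5; adjusted p = 0.275), with the stress transcription factor gene DDIT3 at 1.36 (SE 0.14). Apoptosis regulators were higher in 6 and lower in 4 of 28 (7 and 4; adjusted p = 0.49), with the pro-apoptotic gene HRK at 1.46 (SE 0.17). Oxidative stress genes of NRF2 were higher in 2 and lower in 5 of 18 (2 and 5; adjusted p = 0.121), with the quinone reductase gene NQO1 at -0.71 (SE 0.12). Drug efflux and metabolism genes were lower in 4 of 8 (4; adjusted p = 0.0518), with the transporter gene ABCC3 at -1.43 (SE 0.14). Antigen presentation genes were higher in 1 and lower in 3 of 14 (1 and 3; adjusted p = 0.408), and luminal breast markers lower in 2 of 7 (2, and 1 higher; adjusted p = 0.382). Reference genes were higher in 1 and lower in 1 of 13 (1 and 1; adjusted p = 0.786). Of 17 leukocyte and endothelial markers 4 were measured, under the minimum of 5 for camera, and the macrophage marker gene CD68 rose by 1.21 (SE 0.14) while CD14 fell at -1.03 (SE 0.14).

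The higher dose was compared with the lower one directly. MMP1 was higher at 100 than at 10 nM by 2.91 (SE 0.29, adjusted p = 2.41e-05), MMP3 by 2.22 (SE 0.25), the activity-regulated gene ARC by 1.92 (SE 0.23) and the ribosomal RNA gene RNA28SN5 by 2.39 (SE 0.34), an RNA without a poly(A) tail. S100A9, S100A8 and CCL2 were lower at 100 nM, at -3.21 (SE 0.16), -3.10 (SE 0.20) and -2.96 (SE 0.19), although at 10 nM against DMSO they stood at 0.61 (SE 0.16, adjusted p = 0.062), 0.47 (SE 0.20, adjusted p = 0.325) and 0.37 (SE 0.19, adjusted p = 0.447). The serum amyloid genes SAA1 and SAA2, near-identical copies, were lower by the same comparison at -1.94 (SE 0.19) and -2.49 (SE 0.18), and LCN2 at -2.22 (SE 0.23). In all, 1179 genes differed between the doses, 579 higher and 600 lower at 100 nM. Of the 292 genes called at 10 nM, 247 were called in the same direction at 100 nM and 4 in the opposite direction, and 985 of the 2648 genes called at 100 nM were also called between the doses in the same direction. Of the genes higher at 10 nM than in DMSO 30 were lower at 100 than at 10 nM, and 4 lower at 10 nM than in DMSO were higher at 100 than at 10 nM. Both comparisons use the same 10 nM arrays, whose noise favours such turns. Named after the values were seen, the 30 included IL6 at -1.18 (SE 0.14), PTGS2 at -1.19 (SE 0.32), CSF3 at -0.72 (SE 0.16) and CCL20 at -0.63 (SE 0.12) between the doses. The count of 1179 was 665 and 681 without array 2 or 3 of the 10 nM group, 563 with only these 2 groups in the fit and 662 with the 5 arrays numbered 1 dropped.

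LY294002 alone, compared with DMSO, lowered genes of secreted inflammatory proteins and of lipid synthesis. S100A8 fell from a mean log2 signal of 9.06 ± 0.16 to 6.94 ± 0.15 (SD, n = 3 each), a change of -2.12 (SE 0.20, adjusted p = 5.49e-05), and S100A9 fell at -1.66 (SE 0.16). The chemokine genes CXCL1 and CCL20 fell at -1.76 (SE 0.15) and -1.30 (SE 0.12), the scavenger receptor gene OLR1 at -1.53 (SE 0.14) and TRIML2 at -1.32 (SE 0.15). CSF3 and IL13RA2 were not detected on any LY294002 array and were at least 2.80-fold and 1.92-fold lower (adjusted p = 5.49e-05 and 0.00204). Among the genes that rose were the histone gene H2BC21 at 1.31 (SE 0.15), PNCK at 1.29 (SE 0.16), the prostaglandin D2 synthase gene PTGDS at 1.25 (SE 0.21), the integrin gene ITGB4 at 1.11 (SE 0.16) and the transcription factor gene KLF2, a FOXO target, at 1.06 (SE 0.11, adjusted p = 8e-05). In all, 138 genes changed, 63 higher and 75 lower, and 1654 had an unadjusted p under 0.05. The count was 82, 64 and 72 without DMSO array 1, 2 or 3, and 83 without LY294002 array 2. It was 23 with only these 2 groups in the fit, 31 with the 5 arrays numbered 1 dropped, and 218 to 317 with another background correction, the authors' value table, the signals as deposited, array weights or another variance model. The calls of IL13RA2, H2BC21, PNCK, PTGDS and ITGB4 ended with the 5 arrays numbered 1 dropped (adjusted p = 0.102, 0.0558, 0.067, 0.15 and 0.143), and that of ITGB4 with only the LY294002 and DMSO arrays in the fit (adjusted p = 0.0839). Dropping them leaves fewer arrays per group, so a call can end without a smaller change. H2BC21 stood at 6.869 and 6.526 on DMSO arrays 2 and 3, and at 7.811 and 8.052 on LY294002 arrays 2 and 3.

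Of the 30 inflammatory and secretory genes 9 fell under LY294002 (14 adjusted over the list alone; median -0.43, camera adjusted p = 2.22e-11), among them CXCL8 at -1.14 (SE 0.13), IL6 at -0.93 (SE 0.14) and IL1B at -0.91 (SE 0.12). Of 20 cholesterol synthesis genes 4 fell (10, and 1 rose, adjusted over the list alone; median -0.41, adjusted p = 1.22e-09). INSIG1 fell at -1.01 (SE 0.12), the acetoacetyl-CoA thiolase gene ACAT2 at -0.82 (SE 0.13) and HMGCS1, which encodes an early enzyme of the pathway, at -0.75 (SE 0.12). Of 13 fatty acid synthesis genes 3 fell (7 adjusted over the list alone; median -0.45, adjusted p = 1.21e-08). Of 19 histone genes 5 rose (8 adjusted over the list alone; median 0.29, adjusted p = 1.67e-08), with H2AC18 at 0.98 (SE 0.11) and H2BC5 at 1.19 (SE 0.13), while the 24 RNAs without a poly(A) tail had a median of -0.04. FOXO targets rose in 3 of 27 cases (12, and 1 lower, adjusted over the list alone; median 0.32, adjusted p = 4.51e-06). ATF4 targets fell in 4 of 31 cases and rose in 1 (8 and 2 adjusted over the list alone; adjusted p = 0.00035), with the serine synthesis genes PSPH at -0.91 (SE 0.15) and PSAT1 at -0.70 (SE 0.11). PI3K pathway components had 1 lower gene of 22 and did not pass (1 adjusted over the list alone; adjusted p = 0.831). With only the LY294002 and DMSO arrays in the fit the calls of IL6, IL1B, ACAT2, HMGCS1, PSPH and PSAT1 ended (adjusted p = 0.0902, 0.0799, 0.0978, 0.0839, 0.0664 and 0.0978). With the 5 arrays numbered 1 dropped those of IL6, ACAT2, HMGCS1, PSPH and PSAT1 ended as well (adjusted p = 0.0785, 0.084, 0.1, 0.102 and 0.0708).

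Lysosome and autophagy, mitosis, and extracellular matrix genes passed camera under LY294002 with its preset correlation only. Their medians were 0.12, -0.13 and 0.14, with adjusted p = 0.0303, 0.0329 and 0.0374, and 0.185, 0.235 and 0.0747 with an estimated correlation. With limma 0 of 33 and 0 of 44 genes of the first lists passed, also when adjusted over the list alone, with 5 higher and 4 lower at an unadjusted p under 0.05. Of the 25 matrix genes 1 rose (4 adjusted over the list alone), the connective tissue growth factor gene CCN2 at 0.83 (SE 0.13). The adjusted p for lysosome and autophagy was 0.0721, 0.077 and 0.31 without DMSO array 2, DMSO array 3 or LY294002 array 1, and for mitosis 0.123, 0.0502 and 0.146 without the same arrays. For the matrix list it was 0.116, 0.073, 0.0527 and 0.107 without DMSO array 1, DMSO array 3, array 1 of the 100 nM group or LY294002 array 2. Each of these lists, and CCN2 (adjusted p = 0.1), also lost its call with the arrays numbered 1 dropped, at 0.145, 0.0638 and 0.164.

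**Figure D2:**
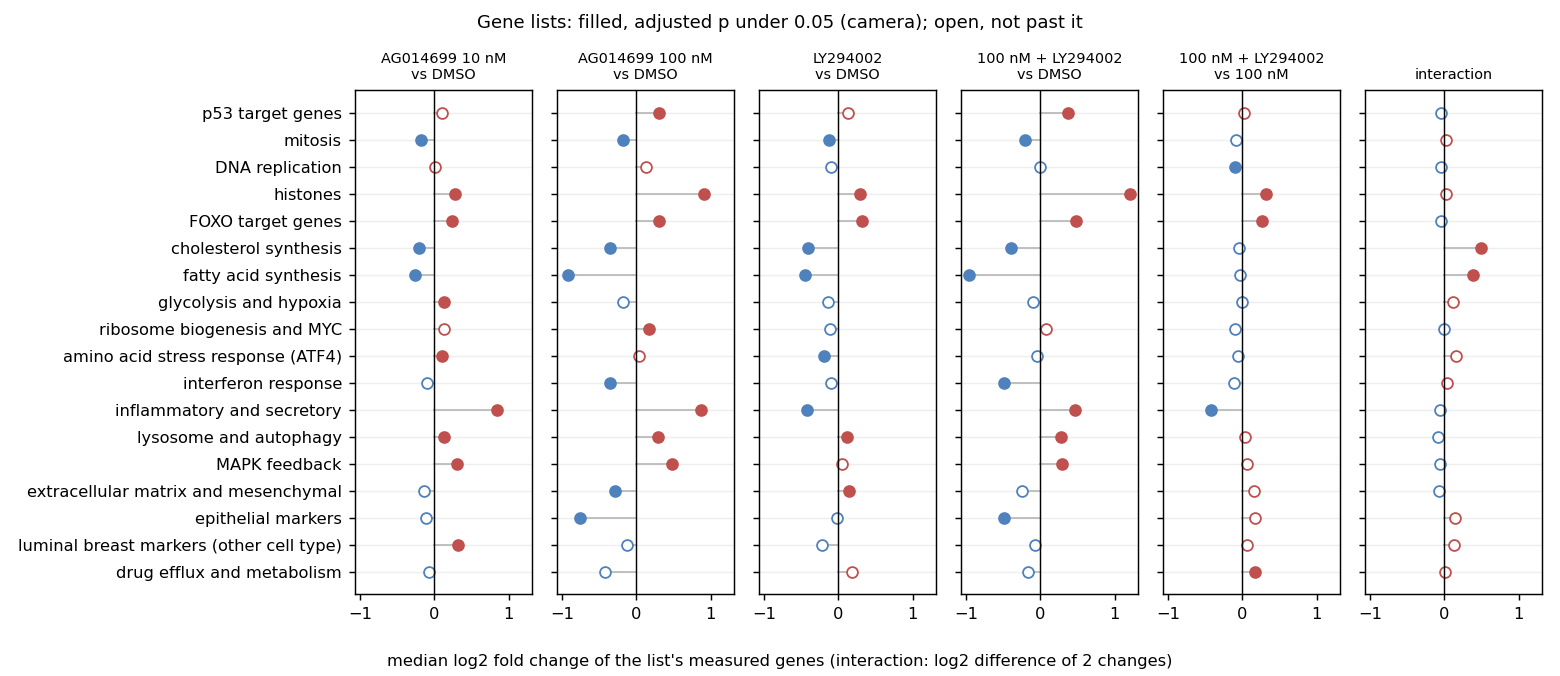
Points show the median log2 change of the measured members of each gene list called in at least 1 of the comparisons, on a horizontal log2 axis with 1 panel per comparison; filled points passed camera at an adjusted p under 0.05 and open points did not. Histones lie at 0.92 and fatty acid synthesis genes at -0.92 for 100 nM AG014699 against DMSO, and both lists move the same ways under LY294002, at 0.29 and -0.45.

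The combination of 100 nM AG014699 with LY294002 was set against DMSO. MMP1 rose by 4.09 (SE 0.29, adjusted p = 1.58e-07), ESM1 by 3.46 (SE 0.20), and the early response genes ARC, FOS and FOSB by 3.17 (SE 0.23), 2.99 (SE 0.24) and 2.98 (SE 0.17). ID2, which encodes an inhibitor of DNA binding by transcription factors, rose by 3.06 (SE 0.17), the reductase gene DHRS2 by 3.01 (SE 0.17) and ANKRD1 by 3.00 (SE 0.27). CFI fell at -3.63 (SE 0.20), S100A9 and S100A8 at -3.36 (SE 0.16) and -3.25 (SE 0.20), S100A4 at -2.90 (SE 0.17) and SAA2 at -2.40 (SE 0.18). CCL2 and the collagen gene COL8A1 were not detected on any array of the combination and were at least 6.65-fold and 4.86-fold lower (adjusted p = 7.4e-08 and 5.5e-08). In all, 2453 genes changed, 1280 higher and 1173 lower, and 1547 changed with the 5 arrays numbered 1 dropped. Of 758 called genes with several probes, 7 had a probe called in the other direction.

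Histone genes rose in 14 of 19 cases under the combination and 1 fell (15 and 1 adjusted over the list alone). Their median was 1.21 (camera adjusted p = 4.79e-13, and 0.000939 with an estimated correlation). H2BC21 rose by 2.79 (SE 0.15), H2BC8 by 2.68 (SE 0.15) and H2AC18 by 2.63 (SE 0.11), and 18 of the 24 RNAs without a poly(A) tail rose beside them, with a median of 1.18. FOXO targets rose in 15 of 27 cases and fell in 1 (17 and 1 adjusted over the list alone; median 0.48, adjusted p = 3.52e-08), among them IRS2 at 1.81 (SE 0.17), BCL2L11, the gene of the pro-apoptotic protein BIM, at 1.40 (SE 0.27) and HBP1 at 1.18 (SE 0.14). Inflammatory and secretory genes rose in 15 of 30 cases and fell in 4 (16 and 5 adjusted over the list alone; median 0.47, adjusted p = 0.000868). IL1B rose by 1.67 (SE 0.12) and CXCL8 by 1.39 (SE 0.13), whereas IL6 was at -0.18 (SE 0.14, adjusted p = 0.414). Lysosome and autophagy genes rose in 10 of 33 cases (12 adjusted over the list alone; adjusted p = 0.000228), with the autophagosome gene MAP1LC3B at 1.04 (SE 0.17). MAPK feedback genes rose in 9 of 22 cases and fell in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.000888). The p53 targets rose in 6 of 25 cases and fell in 2 (11 and 3 adjusted over the list alone; adjusted p = 0.00212), with CDKN1A at 1.77 (SE 0.18).

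Fatty acid synthesis genes fell in 11 of 13 cases under the combination (12 adjusted over the list alone; median -0.96, camera adjusted p = 9.84e-10), with SREBF1 at -2.00 (SE 0.22) and FASN at -1.28 (SE 0.20). Cholesterol synthesis genes fell in 10 of 20 (10, and 2 higher, adjusted over the list alone; adjusted p = 0.000868), with INSIG1 at -0.83 (SE 0.12). Interferon response genes fell in 21 of 37 cases and rose in 3 (23 and 4 adjusted over the list alone; median -0.49, adjusted p = 0.000228), with IFI44L at -2.03 (SE 0.26) and the helicase gene DDX60 at -1.35 (SE 0.20). Epithelial markers fell in 6 of 12 cases and rose in 2 (6 and 2 adjusted over the list alone; adjusted p = 0.0111), with ELF3 at -1.85 (SE 0.13) and CLDN1 at -1.78 (SE 0.18). Mitosis genes fell in 10 of 44 cases (13 adjusted over the list alone; median -0.20, adjusted p = 0.00212, and 0.0931 with an estimated correlation), with SPC25, a gene of the outer kinetochore, at -0.92 (SE 0.15) and KIF20A at -0.81 (SE 0.15). The other 10 of the 11 called lists held with an estimated correlation, and epithelial markers had an adjusted p of 0.107 with every probe tested on its own.

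What LY294002 added to 100 nM AG014699 was tested by setting the combination against AG014699 alone, the comparison closest to the study's question of PI3K inhibition beside PARP1 inhibition. CSF3 fell from a mean log2 signal of 9.51 ± 0.31 to 7.78 ± 0.21 (SD, n = 3 each), a change of -1.73 (SE 0.16, adjusted p = 0.000325). CXCL2 fell at -1.50 (SE 0.19), IL24 at -1.49 (SE 0.18) and CXCL1 at -1.43 (SE 0.15). IL13RA2 fell at -1.40 (SE 0.20), IL6 at -1.38 (SE 0.14, adjusted p = 0.000357) and G0S2 at -1.25 (SE 0.18). MYLIP, the gene of a ubiquitin ligase that targets the LDL receptor, rose by 0.96 (SE 0.14). With the 5 arrays numbered 1 dropped the calls of IL24, IL13RA2, G0S2 and MYLIP ended (adjusted p = 0.0787, 0.155, 0.118 and 0.114), and with only the 2 groups in the fit those of IL13RA2 and MYLIP (adjusted p = 0.118 and 0.0846). In all, 41 genes changed, 13 higher and 28 lower, and 1486 had an unadjusted p under 0.05. The count was 23 and 27 without array 2 or 3 of AG014699 alone and 22, 20 and 20 without array 1, 2 or 3 of the combination. It was 14 with only these 2 groups in the fit, 9 with the arrays numbered 1 dropped, 73 with the strict filter and 87 with another variance model. The split of 13 higher and 28 lower genes was 60 and 69 with quantile normalization and no background correction, 63 and 62 in the authors' value table, 59 and 67 with the signals as deposited, which was chosen after seeing the data, and 38 and 50 with another background correction.

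Among the lists fixed in advance, inflammatory and secretory genes had the median furthest from 0 when LY294002 was added to AG014699. Of the 30 measured members 9 fell (14 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 1.29e-16, and 0.000337 with an estimated correlation). Among the 9 was the IL6-family cytokine gene LIF at -0.97 (SE 0.13), a call that ended with only the 2 groups in the fit (adjusted p = 0.0672) or the arrays numbered 1 dropped (adjusted p = 0.118). Of 19 histone genes 1 rose (7 adjusted over the list alone; median 0.31, adjusted p = 8.4e-07). Of 27 FOXO targets 1 rose (4, and 1 lower, adjusted over the list alone; median 0.26, adjusted p = 4.34e-05). The 24 RNAs without a poly(A) tail had a median of -0.02. The inflammatory, histone and FOXO lists held with an estimated correlation. DNA replication genes lay lower (42 genes, median -0.10, adjusted p = 0.0348) and drug efflux and metabolism genes higher (8 genes, median 0.16, adjusted p = 0.04), with an adjusted p of 0.129 and 0.363 with an estimated correlation. With limma 0 of the 42 and 0 of the 8 genes passed, 4 and 3 had an unadjusted p under 0.05, and 0 and 3 passed when adjusted over the list alone. The adjusted p for DNA replication was 0.145, 0.0728 and 0.118 without array 1 or 2 of AG014699 alone or array 2 of the combination. For drug efflux and metabolism it was 0.247, 0.0728, 0.069 and 0.0902 without array 1 or 2 of AG014699 alone or array 1 or 3 of the combination. Over all settings their adjusted p was at most 0.145 and 0.401. The fatty acid and cholesterol synthesis lists had medians of -0.03 and -0.05 and did not pass (adjusted p = 0.997 each), nor did the p53 targets (adjusted p = 0.991) or the homologous recombination and Fanconi genes (adjusted p = 0.695).

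**Figure D3:**
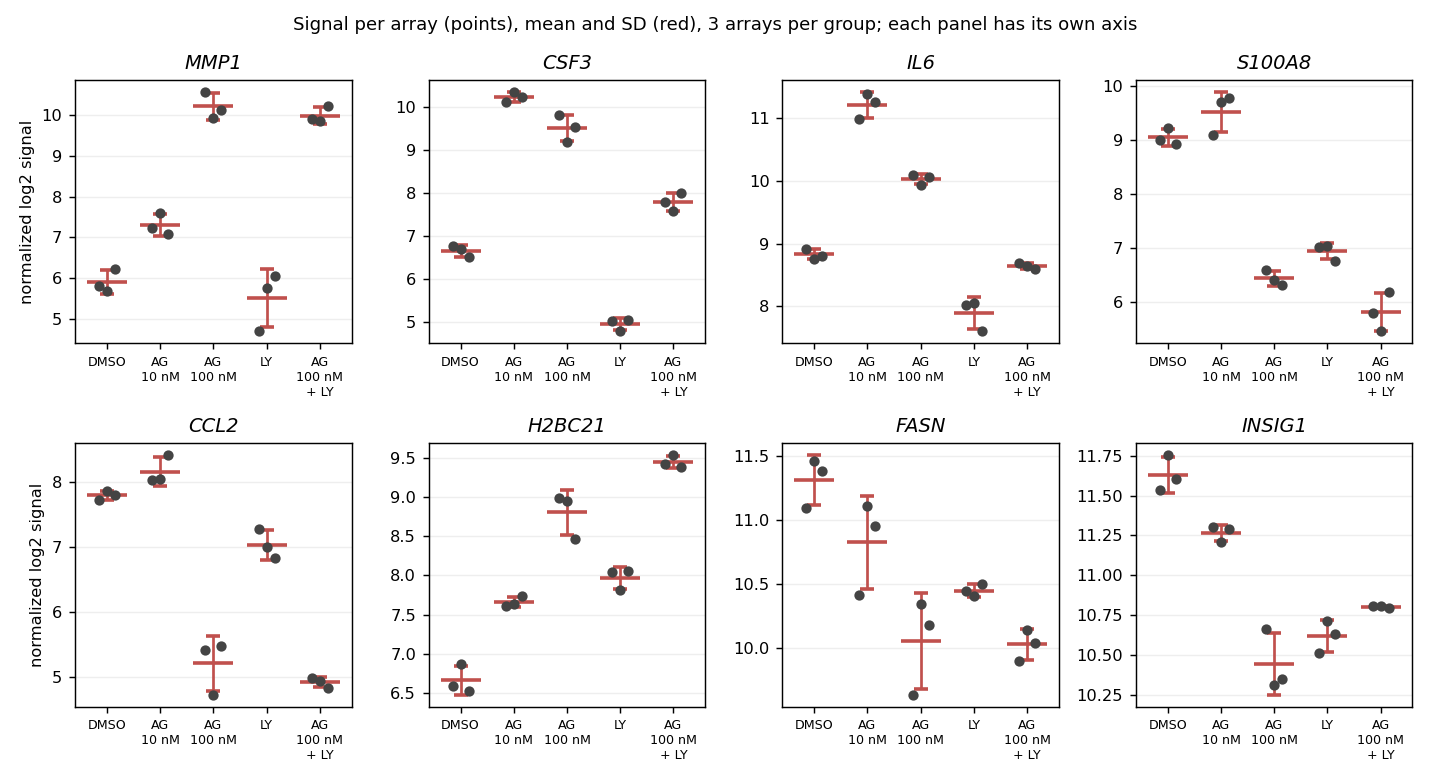
Points show the normalized log2 signal of 8 genes on each of the 15 arrays, and red bars the mean and SD of the 3 arrays of a group; each panel has its own vertical axis. CSF3 averages 6.65 ± 0.13 in DMSO, 10.23 ± 0.12 at 10 nM AG014699, 9.51 ± 0.31 at 100 nM and 7.78 ± 0.21 in the combination.

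What 100 nM AG014699 did on top of LY294002 was tested by setting the combination against LY294002 alone. ESM1 rose by 4.51 (SE 0.20) and MMP1 by 4.49 (SE 0.29) (adjusted p = 4.85e-09 and 9.8e-08), ARC by 2.83 (SE 0.23), CCL20 by 2.79 (SE 0.12) and IL1B by 2.58 (SE 0.12). IL13RA2 and CSF3, undetected on the LY294002 arrays, were at least 9.12-fold and 6.14-fold higher (adjusted p = 2.18e-08 and 3.53e-08). CFI fell at -3.18 (SE 0.20), TGFBI at -2.42 (SE 0.15), TFPI at -2.09 (SE 0.14) and GFRA1 at -2.05 (SE 0.18), and CCL2 was at least 3.92-fold lower (adjusted p = 2.48e-06). In all, 2249 genes changed, 1159 higher and 1090 lower, and 1279 changed with the 5 arrays numbered 1 dropped.

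Whether the effect of LY294002 differed with and without 100 nM AG014699 was tested as an interaction. INSIG1 was the 1 gene of 12302 that passed, at 1.37 (SE 0.17, adjusted p = 0.012), and 889 genes had an unadjusted p under 0.05. It averaged 11.63 ± 0.11 in DMSO, 10.62 ± 0.10 under LY294002, 10.44 ± 0.19 at 100 nM AG014699 and 10.80 ± 0.01 in the combination (log2, SD, n = 3 each). Each agent alone lowered it, and the sum of both changes was not reached. Without DMSO array 2 or 3, array 2 or 3 of AG014699 alone, or array 1, 2 or 3 of the combination, its adjusted p was 0.064, 0.0532, 0.0531, 0.0592, 0.0593, 0.0643 and 0.061, and the count of genes was 0, with 2 genes without array 3 of the 10 nM group. It was 0.0989 for the mean of the INSIG1 probes, 0.0737 with only the 4 groups in the fit and 0.264 with the arrays numbered 1 dropped. The INSIG1 interaction itself was 1.306 to 1.481 with any 1 array left out. For the mean of the probes it was 1.222, and with the arrays numbered 1 dropped 1.473. The count of genes was 0 with only the 4 groups or the arrays numbered 1 dropped, and up to 14 with quantile normalization only. The cholesterol synthesis list had a median interaction of 0.50 (camera adjusted p = 3.61e-07; 1 gene higher, 7 adjusted over the list alone). The fatty acid synthesis list had a median of 0.38 (adjusted p = 2.6e-07; 5 genes higher adjusted over the list alone, and with limma 0 over all genes and 6 at an unadjusted p under 0.05). Both held with an estimated correlation (camera adjusted p = 0.00403 for cholesterol and 0.00323 for fatty acids). The remaining 25 of 27 lists did not pass, among them the inflammatory and secretory genes at a median of -0.06 (adjusted p = 0.709). Other splits of the arrays, with the effect of each drug taken out, did not exclude chance for the 2 lists.

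The responses were also compared across genes, which are not independent replicates. Log2 changes at 10 and 100 nM AG014699 correlated at 0.655, where unchanged groups against the same DMSO arrays gave 0.501 in simulation, with a covariance of 0.0952 against 0.0195. Genes called higher in both numbered 181, against 22.9 for independent lists, and genes called lower in both 66, against 8.44, and 4 were called in opposite directions. The responses to 100 nM AG014699 and to the combination correlated at 0.854 (simulated 0.5; covariance 0.199 against 0.0196), with 913 genes higher in both against 137, 791 lower in both against 127, and 1 called in opposite directions. LY294002 and the combination correlated at 0.351 and LY294002 and 100 nM AG014699 at 0.199. The simulated correlations of 0.501 and 0.5 were for groups without any change. They are no baseline for any of these pairs, since each holds a group that changed strongly. For the pairs with LY294002 alone the covariances were 0.0454 and 0.0266, above the simulated 0.0195 and 0.0196. Genes called higher in both numbered 39 against 6.56 and 27 against 6.74, genes called lower in both 46 against 7.15 and 33 against 8.11, and 12 and 29 were called in opposite directions. Counts for independent lists were computed for calls in the same direction only. Whether opposite calls were also in excess was therefore not assessed, and the shared calls do not show that the responses mainly agree. Of all genes 62.3% and 57.7% had the same sign in both, and the simulated 66.6% is likewise no baseline for them. With 3 DMSO arrays the controls could not be divided so that each part kept at least 2, and part of the excess may come from the shared controls.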

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

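The results here were singled out because the response to LY294002 differed with and without AG014699, or because probes outside the gene table changed; the tests of the DMSO group as a whole, of signals near the floor and of splits with the drug effects taken out were chosen only after the result was seen.

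For the cholesterol and fatty acid synthesis lists the change under the combination was, at the median, less than the sum of both single changes. The interaction was 1.37 for INSIG1, 0.498 as the median of the cholesterol list and 0.383 as the median of the fatty acid list. A single high DMSO array was argued against, since with any 1 DMSO array left out the adjusted p of camera was at most 4.52e-06 for cholesterol and 3.22e-06 for fatty acids. A floor on the signals was argued against as well, with 10% and 7.69% of the members within 1 log2 unit of the detection floor in the combination.

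A DMSO group that stands apart as a whole would raise both lists in DMSO against every treated group. With the 10 nM arrays in place of DMSO the median interaction was 0.280 for cholesterol and 0.239 for fatty acids. With DMSO as the whole cause, 10 nM AG014699 itself would have to raise both lists by these amounts, and its effect cannot be measured without the DMSO arrays, so this stays open for both lists. A shared route by which either drug lowers lipid synthesis, so that the second adds little, is a biological alternative that was not tested further.

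Other splits were counted after the effect of each drug was taken out of the values. For the real count of 1 gene, INSIG1, 2 of 100 splits gave as many, the real one among them, and the highest other was 1. Adjusting the p-values already limits how often any gene passes by chance, so this share adds little to the result for INSIG1. For the real count of 2 lists 14 of 100 splits gave as many, the highest other 3, so chance was not excluded for the lists. Splits of the values as measured, which were planned, carry the effects of both drugs into the interaction and decide nothing. They gave as many genes in 6 of 100 (highest 500) and as many lists in 64 of 100 (highest 14). Planned regroupings within each level of AG014699 keep out its effect but can carry that of LY294002 into the interaction, so they cannot separate chance from it. These regroupings gave as many genes in 10 of 100 (highest 382) and as many lists in 36 of 100 (highest 10).

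Of the 7103 kept probes without a single gene name, 328 changed at 100 nM AG014699 against DMSO, 222 higher and 106 lower. They were not analysed further here.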

How the results depend on the processing

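The signals as deposited and the joint drop of the 5 arrays numbered 1 were alternatives chosen after seeing the data. The joint drop leaves fewer arrays in every group, so calls lost there may reflect fewer arrays and not a smaller change. None of the results turned direction. Of 51 called list results 37 held under every setting, and 357 of 627 named gene results held under every setting in which they were tested. Single genes were not followed with every probe on its own, and some had no value under the authors' value table or the strict filter. Over all settings 16047 of 17513 gene results and 1523 of 1581 list results kept their call, and the remaining 1466 and 58 lost it.

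LY294002 against DMSO, with 138 genes, gave 282 with quantile normalization only, 218 with normexp background, 303 with the authors' value table, 280 with the signals as deposited, 317 with array weights, 238 with a variance trend and robust fit, 23 with only its own groups in the fit, and 31 with the arrays numbered 1 dropped. The combination against AG014699, with 41 genes, gave 129, 88, 125 and 126 under the first 4 of these settings, 73 with the strict filter, 87 with a variance trend, 14 with only its own groups and 9 with the arrays numbered 1 dropped. Its 5 lists were 3 with the strict filter, 3 with an estimated correlation and 3 with the arrays numbered 1 dropped.

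The 292 genes at 10 nM against DMSO were 508 with array weights and 98 with the arrays numbered 1 dropped. The 1179 between doses were 563 with only their own groups and 662 with the arrays numbered 1 dropped. That drop also gave 1547 for the combination against DMSO, 1279 for the combination against LY294002 and 0 for the interaction. The interaction gave 14 genes with quantile normalization only, 6 with normexp, 11 with the authors' value table, 13 with the signals as deposited, 3 with the mean of probes, 2 with array weights, 5 with a variance trend and 0 with only its groups. Its 2 lists were 4 with every probe on its own and 4 with fry, and fry called 21 lists at 100 nM and 17 under the combination against DMSO, where camera called 13 and 11. Over all these settings and arrays left out, INSIG1 had an adjusted p of 5.53e-05 to 0.264 and an interaction of 1.222 to 1.481.

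With 1 array left out in turn the counts ran from 140 to 328 at 10 nM, 1893 to 2931 at 100 nM, 665 to 1345 between doses, 64 to 160 for LY294002, 1758 to 2699 for the combination against DMSO, 20 to 58 against AG014699 with 3 to 5 lists, 1553 to 2342 against LY294002, and 0 to 2 for the interaction.

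The replicate block gave 80 genes for the combination against AG014699, and changes in the remaining counts stayed within 1.5-fold. The main fit was planned without a block. The numbers were not taken as pairs later either, since 1 of 10 pairs of arrays of number 2 correlated above 0.1 after the group means were removed (mean 0.0337). This does not decide against pairing. Residuals cancel within a group, so a number that lies between the others can correlate weakly even where the numbers mark batches. All 10 pairs of number 1 and all 10 of number 3 correlated above 0.1 (means 0.208 and 0.174). Among pairs of different numbers 4 of 60 did, with a mean of -0.0691. For 12 of 15 arrays their own number had the highest mean correlation among the arrays of other groups. These values show structure by number, clear for numbers 1 and 3, that the labels do not name and that the main fit did not take out. A block by BeadChip was not run because the files do not give it.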

Other observations

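The lists of acute phase and immediate early genes, the lists compared between doses, the RNAs without a poly(A) tail and the repeat of the LY294002 response were all chosen only after the result was seen, while the splits of the arrays were planned. Of 11 measured genes of acute phase proteins and calprotectin 2 rose at 10 nM against DMSO (5 adjusted over the list alone) and the other 9 did not pass, with SAA1 at 0.87 (SE 0.19) and SAA2 at 0.83 (SE 0.18). The list had an adjusted p of 0.0532 there with an estimated correlation. At 100 nM 10 fell (11 adjusted over the list alone), with SAA1 at -1.07 (SE 0.19) and SAA2 at -1.65 (SE 0.18). Under the combination 10 fell (11 adjusted over the list alone), with a median of -2.10. Of 21 immediate early genes 9 rose at 10 nM, 14 rose and 1 fell at 100 nM, 4 rose under LY294002 and 15 rose and 1 fell under the combination, with medians of 0.52, 0.81, 0.40 and 1.17 (adjusted over the list alone, 15, 16 and 1, 11 and 1, and 16 and 1). The growth arrest gene GADD45B rose by 1.79 (SE 0.13) at 100 nM and 2.37 (SE 0.13) under the combination.

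Between 10 and 100 nM of AG014699 the fixed lists moved unevenly. Histone genes were higher at 100 nM in 12 of 19 cases and lower in 1 (12 and 1 adjusted over the list alone; median 0.71, camera adjusted p = 1.83e-09). Fatty acid synthesis genes were lower in 8 of 13 cases (10 adjusted over the list alone; median -0.58). Glycolysis and hypoxia genes were lower in 7 of 29 cases (8, and 1 higher, adjusted over the list alone; adjusted p = 0.0011), with ADM at -0.51 (SE 0.11) and NDRG1 at -0.65 (SE 0.14).

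Of 19 histone genes 5 rose under LY294002 and 12 at 100 nM AG014699, and most histone messages lack a poly(A) tail, so a larger share of such RNA in the labelling is a technical candidate. For LY294002 it was argued against, because 24 other RNAs without a poly(A) tail had a median change of -0.038 where the histones had 0.293 and the quartiles of the RNAs lay on average 0.226 from their middle. For 100 nM AG014699 it stays open, because the same RNAs had a median of 1.247 beside 0.915 for the histones. More histone messages with a poly(A) tail in cells that leave the cycle would be a biological alternative that was not tested here.

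The response to LY294002 repeated in part on the AG014699 background. Changes by LY294002 against DMSO and by the combination against AG014699 alone, which share no arrays, correlated at 0.263 across genes, and 57.1% of all genes had the same sign in both, against 50% in simulation. Of 138 genes called under LY294002 122 had the same sign in the second comparison, and CXCL1 fell in both, at -1.76 (SE 0.15) and -1.43 (SE 0.15). In 8 of 200 joint regroupings of the arrays, the real one among them, the correlation was as high, with 0.393 the highest other. That share lies just under 0.05. The rule was set after the result was seen and the replicate numbers went with structure among the arrays, so chance was not excluded.

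For comparisons of a pair of groups 10 splits of 6 arrays exist, which is too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave the real count. Every other split mixes both groups on each side, so a drug effect widens the spread there. Low counts of genes in those splits were thus likely in advance and are no evidence for the real ones. The real and highest other counts of genes were 292 and 0 at 10 nM, 2648 and 0 at 100 nM, 1179 and 0 between doses, 138 and 0 for LY294002, 2453 and 0 for the combination against DMSO, 41 and 0 against AG014699 and 2249 and 0 against LY294002. For lists they were 11 and 5 at 10 nM, 13 and 7 at 100 nM, 9 and 4 for LY294002, 11 and 8 for the combination against DMSO, and 5 and 3 against AG014699.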
